A study of Mus musculus with 18 samples.

How the data were processed

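Gene expression was measured by RNA sequencing in 18 libraries of sorted splenic naive CD4+ T cells from C57BL/6J mice. The libraries fell into 6 groups of 3, by genotype (control or Creld1 cKO) and condition (freshly isolated, 8 h unstimulated culture, 8 h stimulated culture). Groups were taken from the titles and characteristics in the labels. Per the labels' protocols, naive CD4+ T cells were sorted by surface markers, 10 ng of RNA went into each TruSeq version 2 library, a kit that does not mark strand, and single-end reads of 75 bp were made. Alignment, counting and normalization were done before deposit. CASAVA 1.8, HISAT2 2.1.0, SAMtools 1.4, Partek 6.6, DESeq2 and the mm10 build are listed in the submitters' processing notes, with no role or order. The gene annotation and counting settings are not given in the sources used here.

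The deposited values were normalized between libraries and placed on a log2 scale, with 1 value per library for 15137 gene symbols, from -1.36 to 17.2. The method of this transformation is not given in the sources used here. The log2 base was inferred from the values, which sum on the linear scale to between 6782465 and 7419367 per library. The spread between libraries shrank at low levels, the median SD being 0.0871 for genes with a mean below 0 and 0.252 for means of 6 to 8, so differences of low genes may be understated. Whole reads could not be recovered, the depth per library is unknown, and no counting interval was given. No pair of libraries held identical values (0 pairs), and 0 columns belonged to no sample. Of the symbols, 15007 matched the GENCODE M21 annotation of GRCm38, which gave coordinates, transcript length and GC content. GC content was had for 99.1% of tested genes (10782 genes).

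Genes with a linear value of at least 10 in 3 or more of the 18 libraries were tested, 10877 genes or 71.9%. A single model of 6 group means was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3, with trended empirical Bayes moderation, 12 residual degrees of freedom (15.7 with the prior) and no covariate. The design allowed for linear or log values, and since the values were already on a log scale no pseudocount was added. Contrasts gave the genotype effect in each condition and averaged over conditions, the stimulation and culture effects in each genotype, and both interactions. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Creld1 was also adjusted over the 3 conditions alone. Library measures were compared with exact permutation tests, whose smallest p with 3 against 3 is 0.10.

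Gene lists were tested with camera of limma, with a preset correlation of 0.01 between genes and adjustment over the lists. Of 29 lists fixed, 26 had at least 5 tested genes. The lists covered early genes induced by the T cell receptor, cytokines and their receptors, co-stimulatory and inhibitory receptors, naive and quiescence genes, the receptor complex and proximal signalling, calcium entry with calcineurin and NFAT, the Wnt pathway, NF-kB, and cell death. They also covered cell cycle entry, mitosis, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, endoplasmic reticulum stress, heat shock, ribosome biogenesis, cytosolic ribosomal proteins, cholesterol synthesis, amino acid transport with one-carbon metabolism, interferon-stimulated genes and T helper lineages. Markers of memory, regulatory, CD8 T and NK, and myeloid cells were tested, while B cell, red cell and platelet, and sex-linked genes were only described.

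Genes were named by a rule. It took Creld1 everywhere and, per comparison, the 10 largest rises and falls past the threshold with separated libraries and a group mean of at least 100 on the linear scale, without clone-named genes. Where fewer than 5 passed in a direction, genes of smallest p filled up to 5. Within each list the 4 members of smallest p were open to naming, and any called member of the Wnt, NFAT, receptor-induced, naive and camera-called lists. A gene named in 1 comparison could be given in others. The values of some single genes are not reported here.

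The groups, the lists, the rule for named genes, the design and the other settings to be tried were set before the data were examined. These settings were pseudocounts of 5 and 0.5, no filter, a minimum of 50, scaling factors of the TMM type, computed without the planned package and with trims of 30% and 5%, quantile normalization, a fit of only the groups compared, no trend, library weights, a block for runs of library numbers, each library left out in turn, and other list tests. The 2 planned count-based tools could not be run, as whole reads were not recovered. Alternatives with the GC slope of each library as a covariate, with a spline of 4 degrees of freedom on GC content removed from each library, with the block and the GC slope together, and without the pair of libraries farthest from their group in GC slope were chosen after seeing the data. The first component of the residuals was also tried as a covariate during exploration and left out, because fitting a component taken from the residuals inflates the number of calls. The GC slope is computed from the same expression values, so calls made with it as a covariate may be inflated too.

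The limma step was tested on simulated data for 10877 genes, with known changes of each size put into 50 of them. For the genotype effect in fresh cells it recovered 26% of changes of 0.50 log2 units, 78% of 1, and 100% of 2, with 6 false calls. For the stimulation effect in control cells it recovered 34%, 90% and 100%, with 8 false calls. The simulated noise was independent between genes and had the same spread in each group. A deviation of libraries shared by many genes was not simulated, so these rates may not hold for the real libraries. Reads of near-identical copies, overlapping genes and antisense partners may have been split or joined in the authors' counting.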

Results

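RNA sequencing was used to measure gene expression in naive CD4+ T cells sorted from the spleen of C57BL/6J mice, a common inbred laboratory strain. Cells came from control mice or from conditional knockout mice. In the latter, Creld1 was deleted with Cre recombinase driven by CD4 regulatory sequences, which acts in developing and mature T cells. These conditional knockout cells are called Creld1 cKO cells. Creld1 encodes a membrane protein with EGF-like domains. For each genotype, cells were profiled freshly isolated or after 8 h of culture without stimulation. Other cells were profiled after 8 h of culture with antibodies against CD3 and CD28 at 1 µg/ml. These engage the T cell receptor complex and the co-stimulatory receptor CD28. There were 3 libraries in each of the 6 groups, 18 in all. The deposited values were normalized expression values on a log2 scale for 15137 genes, of which 10877 passed the minimum level and were tested. Back on the linear scale they summed to between 6782465 and 7419367 per library, which reflects the normalization, so the sequencing depth behind each value is unknown. The mouse label was identical for the 3 libraries of a group. No label states that they came from separate animals, and the p-values measure only the spread between these libraries, which may be technical.

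Marker transcripts of B cells, cytotoxic T and natural killer cells and myeloid cells were for the most part below the minimum level, reached by 4 of 16, 6 of 16 and 5 of 15 genes with a deposited value, whereas 12 of 13 regulatory and 12 of 22 memory and effector T cell markers reached it. Over the 18 libraries, the mean log2 value was 1.59 for Cd8a of cytotoxic T cells and 2.75 for Lyz2 of myeloid cells, against 12.74 for Cd4. The other CD8 chain gene, Cd8b1, was higher, at 6.41. The regulatory T cell genes Foxp3 and Ikzf2 lay at 5.87 and 6.79 and the memory markers Cd44 and Ly6c1 at 7.55 and 9.02. The B cell genes above the minimum included Cd79a at 4.29 and Cd74 at 4.39. Of the 6 red cell and platelet markers 3 reached the minimum, among them Bpgm at 7.54, whereas the haemoglobin genes Hba-a2 and Hbb-bs lay at 0.46 and 0.61. These 2 lists and the sex-linked genes were too short to test as lists. Some genes on the other marker lists were higher, among them Ctss at 10.00, a lysosomal protease gene, and Klrd1 at 7.82, a receptor gene of natural killer cells. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were expressed in each of the 18 libraries, the lowest value being 8.25 for Uty.

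Creld1 itself (chromosome 6, 113483297 to 113493343, plus strand, GRCm38) was compared first, as a check of the labels. The log2 value of Creld1 was 5.03 ± 0.32 in control and 4.03 ± 0.27 in cKO cells after unstimulated culture (SD, n = 3 each). This difference of -0.999 ± 0.23 (SE) passed the limma test over the 3 conditions (adjusted p = 0.00173), and the 3 cKO libraries all lay below the lowest control library. In freshly isolated cells the values were 4.58 ± 0.26 and 4.10 ± 0.36, a difference of -0.49 ± 0.23 (adjusted p over the 3 conditions 0.0798), with 2 of 3 cKO libraries below the lowest control. In stimulated culture they were 4.74 ± 0.34 and 4.38 ± 0.24, a difference of -0.36 ± 0.23 (adjusted p = 0.138), again with 2 of 3 below. Averaged over the conditions, Creld1 was lower by 34.8% in cKO cells, with a log2 difference of -0.62 and a 95% interval of -0.90 to -0.33. Adjusted over all genes, none of these differences passed (limma adjusted p = 0.790 fresh, 0.103 unstimulated, 0.974 stimulated and 0.344 averaged). The fresh difference passed without control fresh replicate 1 (-0.61, adjusted p over the 3 conditions 0.0465) or Creld1 cKO fresh replicate 3 (-0.64, 0.0322). With the GC slope of each library as a covariate, a setting chosen after seeing the data, the fresh difference was -0.28, the unstimulated difference -0.49 and the stimulated difference -0.52. The last 2 of these passed over the 3 conditions (adjusted p = 0.0204 and 0.00729). With a block for runs of library numbers added to the covariate, the unstimulated difference was -0.45 and did not pass (adjusted p over the 3 conditions 0.0562), while the stimulated difference of -0.54 passed (0.00820). Between stimulated and unstimulated culture Creld1 differed by -0.29 in control and 0.35 in cKO cells, and between unstimulated culture and fresh cells by 0.45 and -0.07 (SE 0.23 for each). The interactions were 0.64 ± 0.33 with stimulation and -0.51 ± 0.33 with culture, and none of these 6 values passed (adjusted p from 0.159 to 0.881). With the GC slope as a covariate the stimulation effect in cKO cells was -0.055 and its interaction -0.037. The stimulation and culture effects in control cells were then -0.019 and 0.16 and the culture interaction -0.20, and with values corrected for GC content the stimulation effect in control cells was 0.00550. The culture effect in cKO cells was 0.086 without Creld1 cKO fresh replicate 3 and 0.042 without Creld1 cKO unstimulated replicate 3. Creld1 was measured at a low level and which exons were deleted is not given in the sources used here, so reads from the remaining exons would count toward it.

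**Figure D1:**
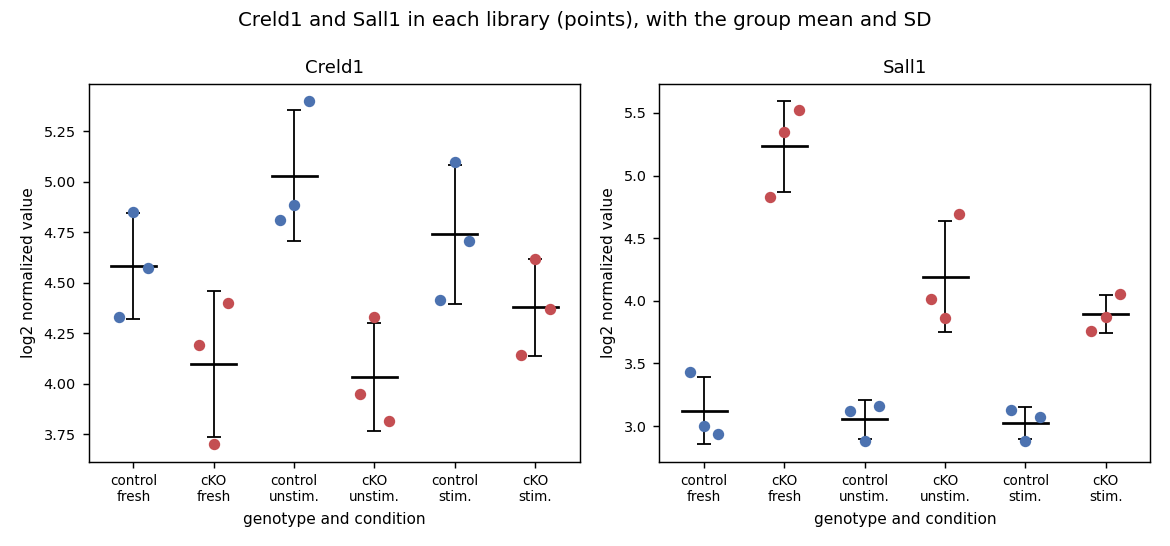
Log2 normalized values of Creld1 and Sall1 in each of the 18 libraries (points) by genotype and condition, with the mean (line) and SD (bars) of the 3 libraries of each group. Creld1 means ran from 4.03 to 5.03 with some overlap between genotypes, whereas the lowest cKO library for Sall1, at 3.76, lay above the highest control library, at 3.43.

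Whether naive cells differed between the genotypes before any culture was tested in the freshly isolated groups. Sall1, which encodes a zinc-finger transcription factor (chromosome 8, 89027235 to 89044162), was 4.32-fold higher in cKO cells, at 5.23 ± 0.36 against 3.12 ± 0.27 in control (SD, n = 3 each; difference 2.11 ± 0.22 SE; limma adjusted p = 5.03e-04). It was the only gene of 10877 past the threshold and lies below the level set for named genes, so it was chosen after its values were seen. Among the genes of smallest p that did not pass, Slfn5 of the Schlafen family differed by 0.38 ± 0.08, the sterol synthesis gene Sqle by 0.31 ± 0.09, the interferon gamma receptor gene Ifngr2 by -0.34 ± 0.08 and the histone chaperone gene Hira by -0.31 ± 0.09 (adjusted p = 0.790 for each).

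As groups in the fresh cells, 5 lists were called, and all 5 calls were lost when the correlation between genes was estimated (adjusted p = 0.772 with an estimated correlation for each). The 14 cytosolic heat shock genes shifted upward (median 0.20; camera adjusted p = 2.49e-04), with Chordc1 at 0.33 and Dnaja1 at 0.32. The 34 interferon-stimulated genes (median 0.09, adjusted p = 0.0357; Ifi44 0.77, Ifit1 0.61) and the 13 mitochondrially encoded genes (median 0.17, adjusted p = 0.0357) also shifted upward. The 23 glycolysis genes (median -0.08, adjusted p = 0.0211; Gapdh -0.34, Tpi1 -0.35) and the 29 naive and quiescence genes (median -0.06, adjusted p = 0.0357; Ccr7 -0.29, Lef1 -0.17) shifted downward. No single member of these 5 lists passed limma's test over all genes or adjusted over the list alone. Sall1 did not pass when only the 6 libraries compared were fitted (adjusted p = 0.398), with the same difference of 2.11 and its error estimated from fewer libraries, or without the pair of libraries farthest from their group in GC slope, which left 1 cKO fresh library (difference 1.70, adjusted p = 0.0606). A minimum of 50 left Sall1 untested, and 0 genes passed. The count of genes was 1193 without Creld1 cKO fresh replicate 3, whose GC slope lay 0.274 above its group mean. The mitochondrially encoded genes (median -0.02, camera adjusted p = 0.605) and the naive and quiescence genes (-0.02, 0.139) were not called with the GC slope as a covariate, which gave -0.15 for Ccr7, -0.11 for Lef1 and -0.15 for Tpi1. The number of lists called was 1 without control fresh replicate 2, 3 without Creld1 cKO fresh replicate 2 or control fresh replicate 3, 1 without the pair farthest in GC slope, again with 1 cKO library, and 8 after quantile normalization.

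In unstimulated culture no gene passed between genotypes, although 3606 of 10877 had an unadjusted p under 0.05 by limma and the smallest adjusted p was 0.0510, shared by Zfp488 (1.01) and Acot4 (0.84), both chosen after their values were seen. Under the rule for named genes, the values in cKO cells were higher for Ahnak, a large scaffold protein gene, by 0.64 ± 0.12 and for Ptpn4, a tyrosine phosphatase gene, by 0.59 ± 0.13 (SE, n = 3 each). The differences were -0.94 ± 0.21 for Trib3, a pseudokinase gene of the stress response, and -0.68 ± 0.14 for Mex3b, an RNA-binding protein gene. They were -0.74 ± 0.15 and -0.74 ± 0.16 for Cox14 and Glrx5, nuclear genes of mitochondrial proteins (adjusted p = 0.103 for each gene from Ahnak to Glrx5). The T cell receptor kinase gene Zap70 differed by -1.07 and the calcium channel gene Orai1 by -1.16, and neither passed. The 13 mitochondrially encoded genes shifted upward (median 0.35, camera adjusted p = 0.00803; mt-Nd5 0.38) and the 35 cytosolic ribosomal protein genes downward (median -0.51, adjusted p = 0.0353; Rplp1 -1.66, Rpl11 -1.68), and both calls were lost with an estimated correlation (adjusted p = 0.982 with an estimated correlation for both). With the GC slope as a covariate, a setting chosen after seeing the data, the mitochondrially encoded genes turned downward (median -0.13, camera adjusted p = 1.85e-05; mt-Nd5 -0.12), and the ribosomal protein genes had a median of -0.04 (0.527; Rplp1 -0.26, Rpl11 -0.36). The covariate left Zap70 at -0.090, Orai1 at -0.098, Trib3 at -0.53, Cox14 at -0.40 and Glrx5 at -0.45. Adjusted over the list alone, 15 ribosomal protein genes were lower and 1 higher, against 0 over all genes. Of 28 tested Wnt pathway genes 0 passed over all genes, and 2 were higher and 6 lower adjusted over the list alone. Of the 2 lists 1 was called without Creld1 cKO unstimulated replicate 1 or control unstimulated replicate 3.

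Measures of composition were also compared between these libraries. The mitochondrial share rests on the mitochondrially encoded genes already given, so it is no separate result. Mitochondrial transcripts took 4.19% ± 0.22 of the linear sum in cKO and 3.27% ± 0.33 in control libraries (SD, n = 3 each), and the GC slope, the change in log2 value per SD of transcript GC content, was -0.13 ± 0.06 against 0.15 ± 0.09. Both measures separated the genotypes fully (two-sided exact permutation p = 0.10 for each, the smallest that 3 against 3 can give). When only these 6 libraries were fitted, 3737 genes passed, 1262 higher and 2475 lower in cKO cells, and without the pair of freshly isolated cKO libraries farthest from their group in GC slope, a setting chosen after seeing the data, 2782 passed. The differences between the genotypes here are the same in these fits as in the main fit. Only the estimated errors, the moderation and the genes tested could move the count. Without control unstimulated replicate 2, 1 gene passed. Between 1 and 5 passed with other pseudocounts, no filter, TMM-type scaling, quantile normalization, no trend or GC-corrected values. With a block for runs of library numbers, which no label ties to a batch, 887 passed, and 0 of these passed with the block and the GC slope together.

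**Figure D2:**
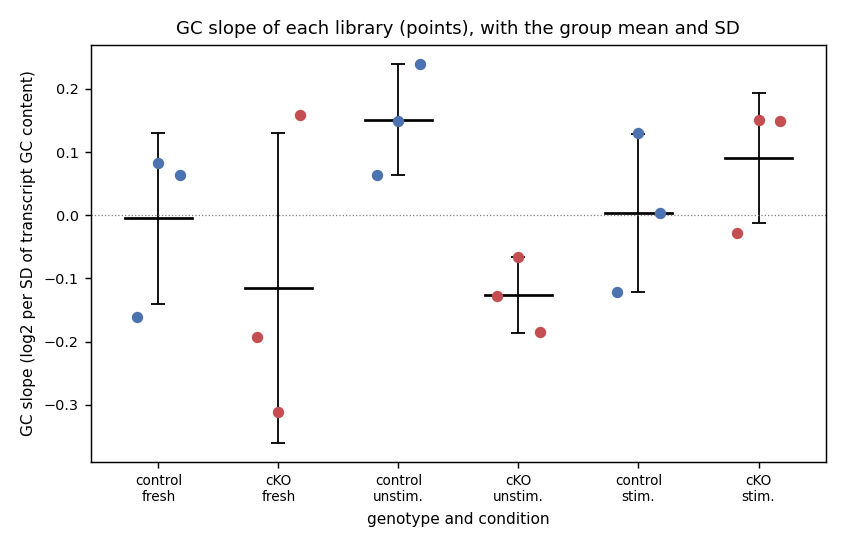
GC slope of each of the 18 libraries (points), in log2 units per SD of transcript GC content, by genotype and condition, with the mean (line) and SD (bars) of the 3 libraries of each group. After unstimulated culture the control libraries lay at 0.06 to 0.24 and the cKO libraries at -0.19 to -0.07, while the genotypes overlapped in the other conditions.

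In stimulated culture 0 of 10877 genes passed between genotypes by limma, 160 had an unadjusted p under 0.05, and the smallest adjusted p was 0.301, for Acot4 (-0.76). The genes of smallest p included Golm1, a Golgi membrane protein gene (0.54 ± 0.12, SE, n = 3 each), Txnrd1, a thioredoxin reductase gene (0.21 ± 0.07), Yars2, a mitochondrial tyrosyl-tRNA synthetase gene (-0.48 ± 0.13), and Pde8a, a phosphodiesterase gene (-0.45 ± 0.15), each with an adjusted p of 0.974. The 27 genes induced early by T cell receptor signalling shifted upward in cKO cells as a group (median 0.22, camera adjusted p = 0.00128, and adjusted p = 0.902 with an estimated correlation), with Nr4a3 at 0.34, Bhlhe40 at 0.30 and Egr3 at 0.28, of which 0 passed singly over all genes or adjusted over the list alone. The 13 mitochondrially encoded genes shifted downward (median -0.16, adjusted p = 0.0138, and adjusted p = 0.902 with an estimated correlation), with mt-Nd6 at -0.19. The early genes had a median of 0.03 (camera adjusted p = 0.302) and the mitochondrially encoded genes of -0.02 (0.901; mt-Nd6 -0.051) with the GC slope as a covariate. The number of lists called was 0 without control stimulated replicate 1 or Creld1 cKO stimulated replicate 3, 1 without Creld1 cKO stimulated replicate 2 and 8 without control stimulated replicate 3.

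Averaged over the 3 conditions, 2 genes were higher in cKO cells and 0 were lower (901 with an unadjusted p under 0.05 by limma). Sall1 was 2.59-fold higher (difference 1.37 ± 0.12 SE, n = 9 libraries per genotype, limma adjusted p = 9.74e-05), with all 9 cKO libraries above all 9 control libraries. Zfp488, a zinc-finger protein gene on chromosome 14 (33967070 to 33978764), was 1.5-fold higher (0.58 ± 0.09, adjusted p = 0.0455). Both were chosen after their values were seen, and the control means of Sall1 lay below the minimum set for testing in each condition. The mouse label differed between conditions but was identical within a group, so it does not settle whether the 9 libraries per genotype are independent. Zfp488 differed by 1.01 in unstimulated culture and 0.59 in stimulated culture, but by 0.14 in fresh cells, or -0.00323 there without control fresh replicate 2 and 0.045 with the GC slope as a covariate. It fell short of the threshold when any single library was left out (adjusted p from 0.0620 to 0.167), except for control fresh replicate 1, control unstimulated replicate 1 and Creld1 cKO fresh replicate 3. Among genes that did not pass, Ahnak differed by 0.39 ± 0.07 and Mbnl1, a splicing regulator gene, by 0.37 ± 0.07 (adjusted p = 0.117 and 0.127), and Lef1, a transcription factor gene of the Wnt pathway and of naive T cells, by -0.19 ± 0.05 (adjusted p = 0.463). Cd4 differed by 0.29 ± 0.07 (adjusted p = 0.448).

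Over the 3 conditions 5 lists were called, and all 5 calls were lost with an estimated correlation (adjusted p = 0.902 with an estimated correlation for each). The naive and quiescence genes (median -0.08, camera adjusted p = 0.0490), glycolysis genes (-0.13, 0.0252) and cytosolic ribosomal protein genes (-0.15, 0.0490) shifted downward. Mitochondrially encoded genes (0.12, 0.0252) and heat shock genes (0.11, 0.0252) shifted upward. With the GC slope as a covariate mitochondrially encoded genes turned downward (median -0.06, camera adjusted p = 7.87e-04), heat shock genes stayed called (0.0027) and the other 3 lists were not called (0.107 to 0.399). Over all genes 0 members passed. Adjusted over the list alone, 1 of 29 naive and quiescence genes was lower. The number of lists called was 1 without control fresh replicate 3, and 3 without Creld1 cKO fresh replicate 1, control unstimulated replicate 1 or 3, control stimulated replicate 1, or Creld1 cKO stimulated replicate 1 or 2. Across the tested genes, the genotype differences of fresh and unstimulated cells correlated with r = 0.63, those of fresh and stimulated cells with r = -0.41 and those of the cultured pair with r = -0.61, where genes are not independent replicates and the conditions share no library. With values corrected for GC content these were 0.36, -0.12 and -0.34. The first was 0.05, and the second 0.03, without Creld1 cKO fresh replicate 2, and the third -0.14 without control stimulated replicate 1. The count of genes was 0 with a minimum of 50, which left Sall1 untested, and 1 with no filter, TMM-type scaling, quantile normalization or without the pair farthest in GC slope. It was 7 with the block for runs of library numbers, 6 with GC-corrected values and 11 with the block and the GC slope. It was 4 without control fresh replicate 1, 1613 without Creld1 cKO fresh replicate 3, 1 or 2 without any other single library and 9, all higher in cKO cells, with the GC slope as a covariate, a setting chosen after seeing the data. Ahnak (adjusted p = 0.0339), Mbnl1 (0.0228), Slfn5 (0.0397) and Cd4 (0.00182) were among them. As the GC slope is computed from the same expression values, these calls may be inflated.

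The response of control cells to 8 h of stimulation was measured against unstimulated culture. Stimulation raised 34 genes and lowered 4 of 10877 by limma, 29 of them by at least 1.5-fold. The transcription factor genes Egr3, Egr1 and Egr2, which T cell receptor signalling induces, rose by 1.46 ± 0.20, 1.25 ± 0.19 and 1.14 ± 0.19 log2 units (SE, n = 3 per group; adjusted p = 0.00527, 0.00803 and 0.0188). Il2ra, the interleukin-2 receptor alpha chain (1.20 ± 0.23, adjusted p = 0.0309), and Irf4, a transcription factor of activated lymphocytes (1.10 ± 0.22, 0.0395), rose as well. Trib3 fell by 1.12 (0.0316), and Tsc22d3, a glucocorticoid-induced leucine zipper gene, fell by 0.50 (0.0475).

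Other genes raised in control cells were the claudin gene Cldn10 (1.13), the chaperone gene Hspa4l (1.10), the serum matrix protein gene Itih5 (0.99), Sytl2 of vesicle transport (0.97) and Bcl2a1b, a survival gene with near-identical copies between which reads could be split (0.84). Rflnb (-0.49) and Arl5c (-0.46) fell. Of 27 tested genes induced early by the receptor, 4 rose and 23 did not pass (6 higher and 1 lower adjusted over the list alone). Of 22 co-stimulatory and inhibitory receptors, 3 rose (Icos 0.83, Btla 0.61, Slamf1 0.69; 7 adjusted over the list alone). In cholesterol synthesis 2 of 23 rose (Idi1 0.61, Cyp51 0.47; 7 adjusted over the list alone), and in ribosome biogenesis 0 of 30 passed over all genes and 8 were higher adjusted over the list alone (Gnl3 0.51, Tsr1 0.47). Of 13 cytokine and cytokine receptor genes 2 rose, Il2ra and Il6st (0.48), with 4 higher and 2 lower adjusted over the list alone. Malt1 of receptor signalling (0.62) and Ccr4 of T helper cells (1.67) rose too.

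By camera, 11 lists were called in stimulated control cells. None of the 11 held with an estimated correlation, the lowest being co-stimulatory receptors (adjusted p = 0.0939 with an estimated correlation) and the highest mitochondrially encoded genes (adjusted p = 0.602 with an estimated correlation). Of these, 10 shifted upward, including co-stimulatory receptors (median 0.26, adjusted p = 3.37e-07), ribosome biogenesis (0.18, 3.37e-07), cholesterol synthesis (0.21, 5.23e-05), early receptor-induced genes (0.19, 1.27e-04) and amino acid transport and one-carbon metabolism (0.11, 0.00258; Psat1 0.46). The other 5 were heat shock genes (adjusted p = 0.0146), mitochondrially encoded genes (0.0146), cell death and survival (0.0177), receptor complex and proximal signalling (0.0362) and regulatory T cell markers (0.0362), whose members Il2ra, Tnfrsf9 and Ctla4 are also activation genes. Naive and quiescence genes shifted downward (median -0.14, adjusted p = 0.00205; Txnip -0.31, Pik3ip1 -0.42). The mitochondrially encoded genes had a median of -0.05 and were not called with the GC slope as a covariate (camera adjusted p = 0.202). The count of genes was 9, 12 and 15 without control unstimulated replicate 1, 2 or 3, and 78, 6 and 4 without control stimulated replicate 1, 2 or 3, and that of lists was 7 without the last of these. The gene count was 7 when only the 6 libraries were fitted, 60 after quantile normalization, 321 with the GC slope as a covariate, 131 with GC-corrected values and 240 with the block and the GC slope. Without the pair of libraries farthest in GC slope, both freshly isolated, it was 98.

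**Figure D3:**
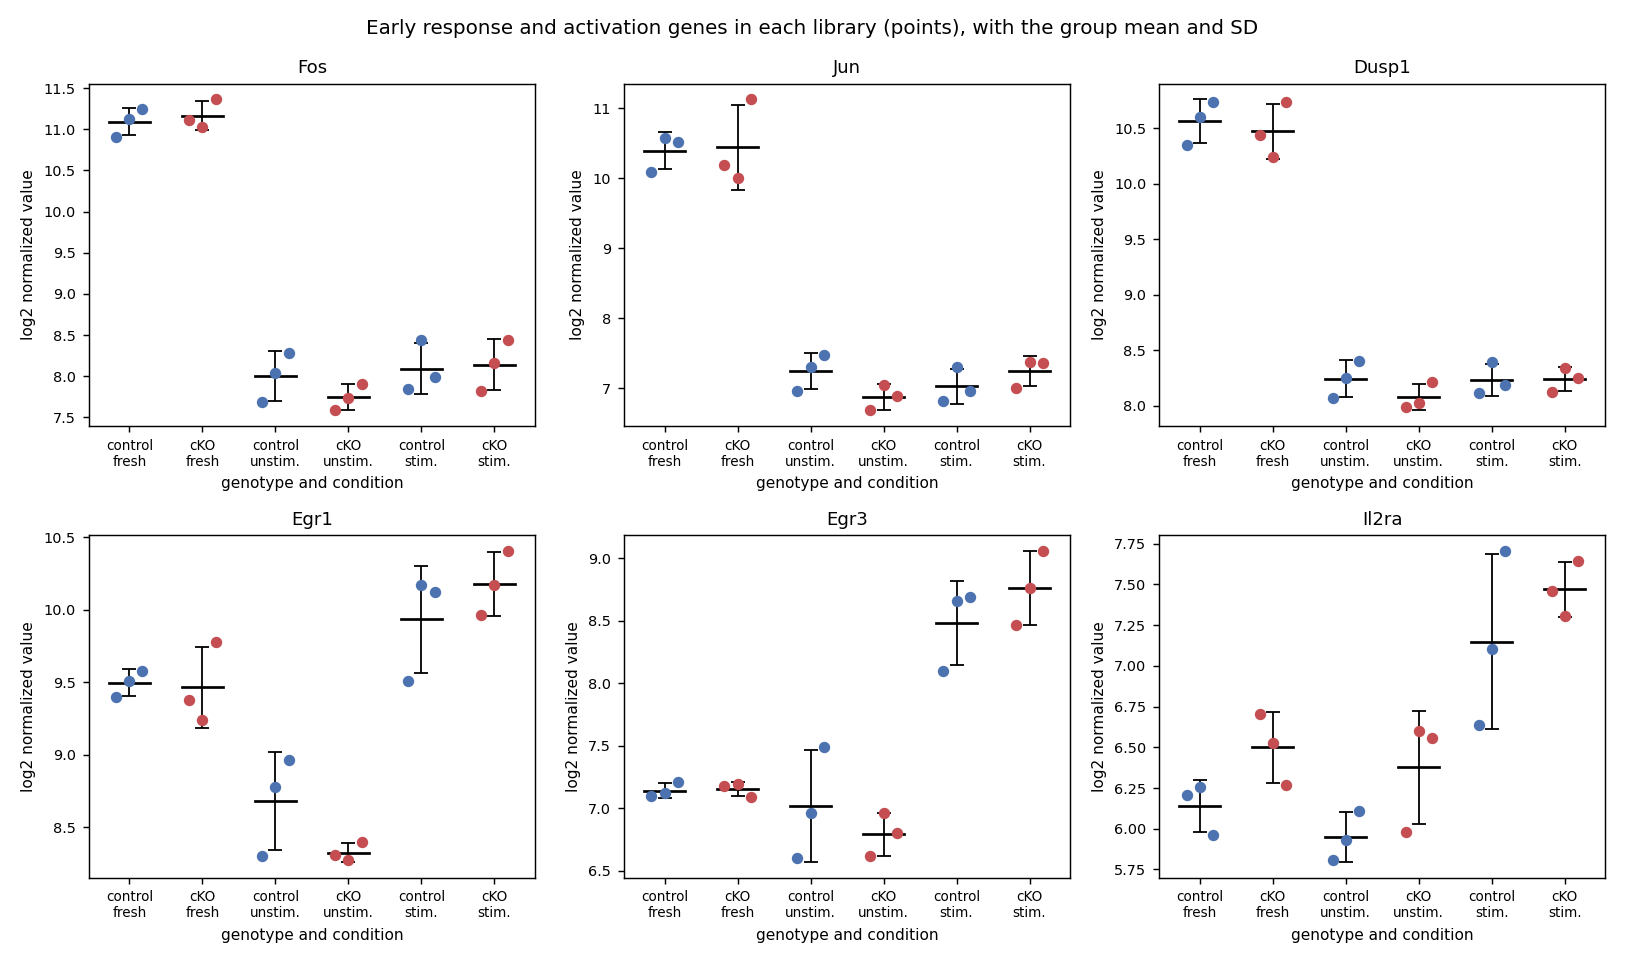
Log2 normalized values of Fos, Jun, Dusp1, Egr1, Egr3 and Il2ra in each library (points) by genotype and condition, with the mean (line) and SD (bars) of the 3 libraries of each group. Fos lay at 10.91 to 11.36 in fresh cells and at 7.59 to 8.44 in the cultured groups, while Egr3 was highest in the stimulated groups, at 8.10 to 9.06.

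In Creld1 cKO cells stimulation raised 30 genes and lowered 1 of 10877 by limma, 25 of them by at least 1.5-fold. Egr3, Egr1 and Egr2 rose by 1.97 ± 0.20, 1.86 ± 0.19 and 1.38 ± 0.19 (SE, n = 3 per group; adjusted p = 2.84e-04, 2.84e-04 and 0.00304). The inflammatory cytokine gene Tnf rose by 1.25 ± 0.16 (adjusted p = 0.00190), and Gfi1, a transcriptional repressor gene, by 1.19 ± 0.21 (0.0219). Hivep3 (1.78), the adaptor gene Sh3bp2 (1.69), the lipid transfer gene Pitpnm2 (1.49), Tacc2 (1.01) and the tubulin gene Tuba1c (0.94) rose too. Acot4, an acyl-CoA thioesterase gene below the level set for named genes and chosen after its values were seen, was the 1 gene that fell, by 1.02 (adjusted p = 0.00185). Il2ra, at 1.09, did not pass in cKO cells (adjusted p = 0.0525).

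By camera, 11 lists were called in cKO cells. None of these 11 calls held with an estimated correlation, the lowest adjusted p being 0.234 with an estimated correlation, for cholesterol synthesis among others, and the highest 0.520 with an estimated correlation, for ribosomal proteins. Of the 27 early receptor-induced genes, 3 rose in cKO cells and 14 were higher adjusted over the list alone (Nr4a3 0.88; median 0.57; camera adjusted p = 1.84e-10, and adjusted p = 0.275 with an estimated correlation). Of 22 co-stimulatory and inhibitory receptors 1 rose, Slamf1 by 0.70, and 9 were higher and 1 lower adjusted over the list alone (camera adjusted p = 6.19e-04, and adjusted p = 0.234 with an estimated correlation). Cholesterol synthesis (Cyp51 0.48; adjusted p = 1.83e-04), ribosome biogenesis (3.26e-05; 14 of 30 higher adjusted over the list alone), amino acid transport (0.00238; Slc7a5 0.83) and glycolysis (0.00238; Ldha 0.40) shifted upward. So did regulatory T cell markers (0.00203), receptor complex genes (0.00844; Lcp2 0.45), cytosolic ribosomal proteins (0.0186) and cytokines and their receptors (0.0354). Mitochondrially encoded genes shifted downward (0.00238; median -0.30). The stimulated cKO libraries had a lower mitochondrial share of the linear sum, 3.36% ± 0.40 against 4.19% ± 0.22, and a higher GC slope, 0.09 ± 0.10 against -0.13 ± 0.06 (SD, n = 3 each; two-sided exact permutation p = 0.10 for each). The mitochondrially encoded genes turned upward with the GC slope as a covariate (median 0.07, camera adjusted p = 0.0257), while ribosomal proteins (0.440), cytokines (0.195) and glycolysis (0.0615; Ldha 0.18) were not called and Slc7a5 lay at 0.39. The count of genes was 12, 13 and 11 without Creld1 cKO unstimulated replicate 1, 2 or 3, 13 without stimulated replicate 2 or 3, 2349 when only the 6 libraries were fitted and 72 with the GC slope as a covariate. It was 183 with GC-corrected values, 153 with the block for runs of library numbers and 139 with the block and the GC slope. Without the pair of libraries farthest in GC slope it was 139.

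Whether stimulation acted differently in the genotypes was tested as an interaction. Acot4 (chromosome 12, 84038379 to 84048601) was the only gene of 10877 past the threshold, 3049 having an unadjusted p under 0.05. With stimulation it differed by 0.58 ± 0.13 in control (adjusted p = 0.0869) and fell by 1.02 ± 0.13 in cKO cells, an interaction of -1.60 ± 0.18 (SE, n = 3 libraries per group; limma adjusted p = 0.00247). Its levels were 4.58 ± 0.25 and 5.15 ± 0.14 in control and 5.41 ± 0.08 and 4.39 ± 0.08 in cKO cells (SD). Acot4 was chosen after its values were seen, and it overlaps an antisense gene that libraries without strand information cannot separate. Of the genes raised by stimulation, 12 rose in both genotypes (independent lists would share 0.0938), among them the Egr genes, Ccr4 (1.67 control, 1.72 cKO), Slamf1 and Cyp51.

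By camera, 3 lists were called, and the 3 calls were lost with an estimated correlation (adjusted p = 0.893 with an estimated correlation for each). The 35 cytosolic ribosomal protein genes (median 0.65, camera adjusted p = 0.0493; Rplp1 2.13) and the 27 early receptor-induced genes (0.44, 0.0493; Ier2 1.29) had a positive interaction, the response in cKO minus that in control cells. The 13 mitochondrially encoded genes had a negative one (median -0.49, adjusted p = 0.00262; mt-Nd4l -0.60). Of the members, 0 passed over all genes or adjusted over the list alone. With the GC slope as a covariate the early genes turned to a negative interaction (median -0.13, camera adjusted p = 0.00917; Ier2 -0.13) and the mitochondrially encoded genes to a positive one (0.11, 0.00521; mt-Nd4l 0.043), and the ribosomal protein genes lay at -0.00111 (0.803; Rplp1 0.30). Genes of smallest p that did not pass included Trib3 (1.33 ± 0.30), the glycogen synthase gene Gys1 (1.02 ± 0.23) and Ptpn4 (-0.76 ± 0.19; adjusted p = 0.166 for each), of which Trib3 was 0.80 and Gys1 0.58 with the covariate. Across all tested genes the responses of the genotypes correlated with r = -0.46, or -0.0740 with values corrected for GC content, and across the 57 genes called in either genotype with r = 0.64, where 55 had the same sign. The first of these was -0.14 without control stimulated replicate 1. The number of lists called was 1 without Creld1 cKO unstimulated replicate 1, Creld1 cKO stimulated replicate 2 or 3, control stimulated replicate 1 or control unstimulated replicate 3. Acot4 fell short of the threshold with a block for runs of library numbers together with the GC slope (adjusted p = 0.0549), and a minimum of 50 left it untested. With the GC slope alone as a covariate its interaction was -1.61 (limma adjusted p = 0.0104). Without a filter 3 genes passed. A total of 1384 genes passed without the pair of libraries farthest in GC slope, 2373 when only the 12 cultured libraries were fitted.

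The effect of culture without stimulation was measured against freshly isolated cells. In control cells, 8 h without stimulation raised 1619 and lowered 1532 of 10877 genes by limma, 1330 of them by at least 1.5-fold and 296 by at least 2-fold. The AP-1 transcription factor genes Jun, Fos (chromosome 12, 85473890 to 85477273) and Fosb fell, with log2 differences of -3.15, -3.09 and -3.08 (SE 0.24, 0.18 and 0.23; n = 3 per group; adjusted p = 2.35e-07, 2.08e-08 and 1.38e-07). Among the other genes with the largest falls under the rule for named genes were Tnfaip3, an inhibitor of NF-kB (-2.37), the phosphatase gene Dusp1 (-2.32), the kinase gene Sik1 (-2.41) and Ppp1r15a of the stress response (-2.29), together with Klf4 (-2.52), Igfbp4 (-2.68) and the coronin gene Coro2a (-2.34). The insulin-like growth factor receptor gene Igf1r rose by 1.71 ± 0.09, the zinc transporter gene Slc39a4 by 2.07 ± 0.24 and Trib3 by 1.77 ± 0.21. Rises were also found for the collagen receptor gene Ddr1 (1.72 ± 0.32), the kinesin genes Kif3a (1.71 ± 0.12) and Kif22 (1.64 ± 0.14) and the phosphate transport gene Ank (1.72 ± 0.08). Fam221a (1.72 ± 0.12), Wfikkn2 (1.64 ± 0.34) and Btbd2 (1.61 ± 0.47, or 0.90 with the GC slope as a covariate) rose too.

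Interferon-stimulated genes fell together after culture. Of 34 tested, 25 fell and 9 did not pass, with 27 lower adjusted over the list alone (Oas2 -2.02, Mx1 -1.46, Rtp4 -1.45; median -0.66; camera adjusted p = 4.38e-13, or adjusted p = 0.0157 with an estimated correlation). Of 14 cytosolic heat shock genes 12 fell, also adjusted over the list alone (Dnajb4 -1.47, Hsph1 -1.18, Hspa8 -1.07; adjusted p = 3.85e-09, or adjusted p = 0.0446 with an estimated correlation). Of 27 genes of endoplasmic reticulum stress and folding 12 fell and 2 rose, 13 and 2 adjusted over the list alone (the chaperone genes Hspa5 -1.62 and Dnajb9 -2.17; adjusted p = 2.73e-04, or adjusted p = 0.0304 with an estimated correlation). Of 27 early receptor-induced genes 11 fell and Irf4 rose (0.63), 12 and 1 adjusted over the list alone. The activation marker gene Cd69 (-1.94) and the phosphatase gene Dusp5 (-1.85) were among them (camera adjusted p = 2.33e-05, and adjusted p = 0.555 with an estimated correlation). Of 30 ribosome biogenesis genes 13 fell and 1 rose, 15 and 1 adjusted over the list alone (Gnl3 -1.31, Nop56 -0.73; adjusted p = 1.98e-05, and adjusted p = 0.183 with an estimated correlation).

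Smaller shifts downward were found in control cells for receptor complex and proximal signalling genes (8 of 27 fell, 2 rose; adjusted p = 0.0159, and adjusted p = 0.285 with an estimated correlation) and nuclear-encoded oxidative phosphorylation (5 of 30 fell; adjusted p = 0.0118, and adjusted p = 0.392 with an estimated correlation). Mitochondrially encoded genes (2 of 13 fell; adjusted p = 0.0119, and adjusted p = 0.725 with an estimated correlation) and amino acid transport (7 of 22 fell, 1 rose; adjusted p = 0.0119, and adjusted p = 0.285 with an estimated correlation) shifted downward too. The mitochondrially encoded genes were not called with the GC slope as a covariate (adjusted p = 0.160). Mitochondrial transcripts took 4.11% ± 0.80 of the linear sum in fresh and 3.27% ± 0.33 in unstimulated control libraries (SD, n = 3 each). The two-sided exact permutation p was 0.10, the smallest that 3 against 3 can give. Adjusted over the list alone, the counts of these lists, in the order given, were 9 and 2, 4 and 0, 2 and 0, and 7 and 1. The other lists were not called. Of 29 naive and quiescence genes, 10 rose and 6 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.853). The transcription factor genes Tcf7 (0.34, or 0.21 with the covariate) and Lef1 (0.42) and the survival receptor gene Il7r (0.50) rose, while Klf6 (-1.42), Cxcr4 (-1.23) and Foxo1 (-0.76) fell. In the Wnt pathway 6 rose and 9 fell of 28 (7 and 10 adjusted over the list alone; adjusted p = 0.825; Ctnnb1 0.56, Gsk3b -0.54, Rnf43 -0.89), and in calcium entry and NFAT 4 rose and 9 fell of 29 (also adjusted over the list alone; adjusted p = 0.356; Orai3 0.85, Rcan3 0.56, Nfatc2 -0.46).

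The remaining lists were not called either, camera adjusted p being 0.141 for cytokines and their receptors (1 rose and 5 fell of 13), 0.350 for co-stimulatory receptors (2 and 6 of 22; Ctla4 -1.24, Cd40lg -0.91) and for glycolysis (1 and 4 of 23), and 0.382 for cell death (5 and 7 of 28; Bcl2 -0.88) and for ribosomal proteins (0 and 6 of 35). It was 0.655 for cell cycle entry (5 and 6 of 35; Cdkn1a 1.00, Ccnd2 -0.86) and 0.95 for NF-kB (5 and 4 of 23; Relb 1.25), cholesterol synthesis (2 and 4 of 23) and mitosis (1 and 2 of 17). For T helper lineage genes it was 0.429 (4 and 5 of 21), for regulatory T cell markers 0.429 (2 and 3 of 12), for memory and effector markers 0.398 (2 and 3 of 12; Cd44 -1.35), and for the markers of CD8 T and NK cells (1 and 2 of 6) and myeloid cells (1 and 2 of 5) 0.935. Adjusted over the list alone these counts stood as given, except for cytokines (1 and 6), ribosomal proteins (0 and 2), mitosis (1 and 1) and memory markers (2 and 4). With library weights, whose estimation stopped before convergence, 6444 genes passed in control cells. In the other comparisons these weights gave 7292 genes between genotypes in unstimulated and 2344 in stimulated culture, 3569 on average, 6301 and 6169 for stimulation in control and cKO cells and 7103 for its interaction.

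**Figure D4:**
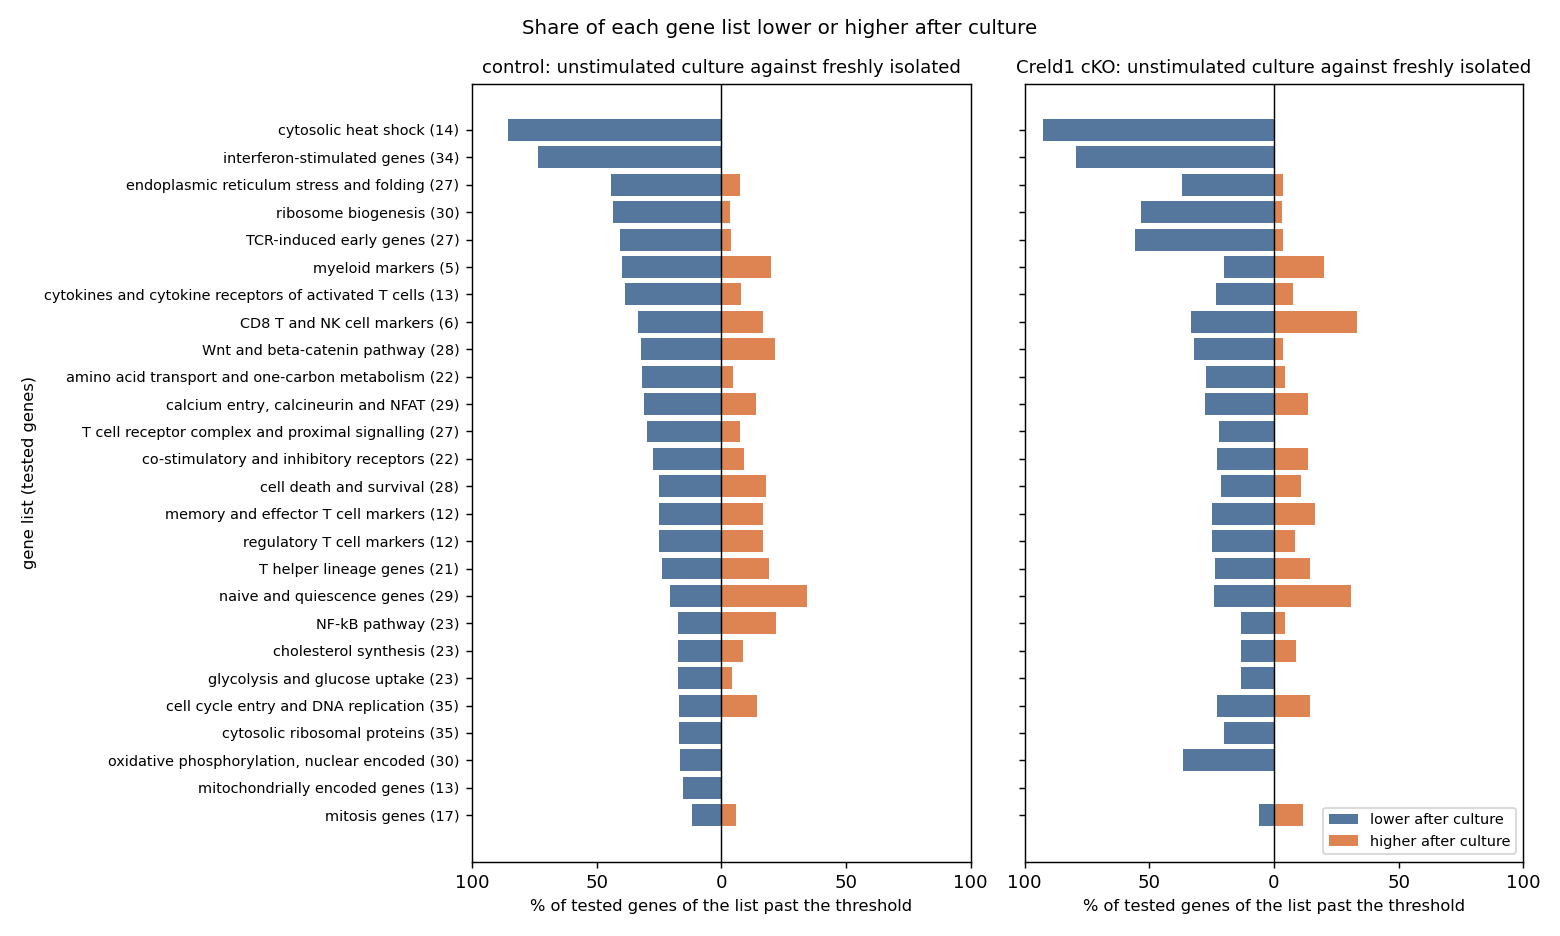
Percentage of the tested genes of each of 26 gene lists that were lower (left of 0) or higher (right of 0) past the threshold after unstimulated culture against freshly isolated cells, in control (left) and Creld1 cKO cells (right); the number of tested genes stands beside each list. Heat shock and interferon-stimulated genes had the highest shares lower, with 12 of 14 and 25 of 34 in control and 13 of 14 and 27 of 34 in cKO cells.

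In Creld1 cKO cells culture raised 1164 and lowered 1244 of 10877 genes by limma, 929 of them by at least 1.5-fold and 213 by at least 2-fold. Jun, Fos, Junb and Fosb fell, with log2 differences of -3.57, -3.42, -2.92 and -2.91 (SE 0.24, 0.18, 0.66 and 0.23; n = 3 per group; adjusted p = 5.83e-08, 7.59e-09, 0.00466 and 3.14e-07). Sik1 (-2.75), Igfbp4 (-2.74), Klf4 (-2.49), Dusp1 (-2.40), Ppp1r15a (-2.34) and Coro2a (-2.30) fell as well. Igf1r rose by 1.8 ± 0.09, Kif3a and Fam221a each by 1.71 ± 0.12. Tnfrsf26 and Tnfrsf23 of the tumour necrosis factor receptor family, the second of which resembles Tnfrsf22 closely enough for reads to be split between them, rose by 1.65 ± 0.11 and 1.61 ± 0.15. The nutrient-sensing GTPase gene Rragd rose by 1.56 ± 0.18, Ank by 1.5 ± 0.08, the transcription factor gene Ikzf4 by 1.4 ± 0.15, Kcnip2 by 1.38 ± 0.18 and Trim5 by 1.36 ± 0.12. Of the genes called, 842 rose in both genotypes and 956 fell in both, where independent lists would share 173 and 175. Across all tested genes the culture effects correlated with r = 0.74.

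Of 34 interferon-stimulated genes 27 fell in cKO cells, also adjusted over the list alone (Oas2 -1.97, Oas3 -1.74, Ifit1 -1.70; camera adjusted p = 2.14e-17, or adjusted p = 0.00474 with an estimated correlation). Of 14 heat shock genes 13 fell, also adjusted over the list alone (Hsph1 -1.31, Dnaja1 -1.16; 3.52e-12, or adjusted p = 0.0164 with an estimated correlation). Of 27 endoplasmic reticulum stress genes 10 fell and 1 rose, 13 and 1 adjusted over the list alone (Hspa5 -1.69, Atf4 -1.15; 9.74e-06, or adjusted p = 0.00896 with an estimated correlation). Of the early receptor-induced genes 15 of 27 fell and Irf4 rose (0.78), also adjusted over the list alone (Cd69 -1.83, Nr4a1 -1.65, Ier2 -1.17, Myc -0.79; 1.51e-07, and adjusted p = 0.343 with an estimated correlation). Of ribosome biogenesis genes 16 of 30 fell and 1 rose, 19 and 1 adjusted over the list alone (5.46e-06, and adjusted p = 0.151 with an estimated correlation). Oxidative phosphorylation (11 of 30 fell; Cox6c -0.59; adjusted p = 5.57e-04), ribosomal proteins (7 of 35 fell, 6 adjusted over the list alone; Rps2 -0.55; 0.00355), amino acid transport (6 of 22 fell and 1 rose; 0.0101) and receptor complex genes (6 of 27 fell; 0.0197) shifted downward too. These 4 lost the call (adjusted p = 0.235, 0.639, 0.240 and 0.240 with an estimated correlation). In the Wnt pathway 1 rose and 9 fell of 28 (Ctnnb1 0.57, Tle3 -0.82) with no call (adjusted p = 0.260). The count of genes was 4940 with the GC slope as a covariate, 3776 with GC-corrected values, 5009 with the block and the GC slope and 811 when only the 6 libraries were fitted.

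Whether culture acted differently in the genotypes was tested as an interaction, in which 0 of 10877 genes passed by limma (545 with an unadjusted p under 0.05; smallest adjusted p = 0.299; 1 gene with the block and the GC slope), and 0 of the 26 lists passed by camera. The genes of smallest p were Gpr107 (0.64 ± 0.15), Klf10, a transforming growth factor beta response gene (0.59 ± 0.15), Mex3b (-0.87 ± 0.19), the co-repressor gene Tle3 (-0.68 ± 0.18), the proteasome subunit gene Sem1 (-0.45 ± 0.12) and the mitochondrial ribosome gene Mrpl51 (-0.74 ± 0.20; SE, n = 3 libraries per group; adjusted p = 0.843 for each). Fos (-0.33 ± 0.26, adjusted p = 0.847; -0.11 with the GC slope as a covariate) and Oas2 (0.05 ± 0.14, 0.940) fell in both genotypes, and the difference between these falls did not pass. For Oas2 it was -0.029 without control unstimulated replicate 1 and -0.013 without Creld1 cKO unstimulated replicate 2.

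For every list that camera called, the median, the mean and the direction of the test had the same sign. Among lists not called they differed in sign after culture in control cells for co-stimulatory receptors, naive and quiescence genes, Wnt, NF-kB, mitosis, glycolysis, ribosomal proteins, cholesterol synthesis, CD8 T and NK cell and myeloid markers, and in cKO cells for co-stimulatory receptors, naive and quiescence genes, cell cycle entry, mitosis, CD8 T and NK cell and myeloid markers. With stimulation they differed for calcium entry and NFAT in both genotypes, for glycolysis and endoplasmic reticulum stress in control cells, and for memory markers in cKO cells. Between genotypes they differed in fresh cells for Wnt, memory, CD8 T and NK cell and myeloid markers, and in stimulated culture for naive and quiescence genes, oxidative phosphorylation and heat shock genes. In unstimulated culture they differed for cytokines, co-stimulatory receptors, cell death, cell cycle entry, oxidative phosphorylation, ribosome biogenesis, cholesterol synthesis, interferon-stimulated and T helper genes.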

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

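The tests on GC content, on runs of library numbers and on the block together with the GC slope were chosen only after the result was seen. The splits of the libraries were planned. The test for a genotype effect apart from the GC trend was written before its result was seen. It used the removal of the GC trend, which was chosen after seeing the data, and the genes called with the block.

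Stimulation acted differently in the 2 genotypes for Acot4, by the interaction test. Its difference of responses was -1.60 (limma adjusted p = 0.00247). Of 100 splits of the genotypes 2 gave as many genes, a share under 0.05, the highest other split giving 1. The splits count genes and do not test Acot4 itself, which was chosen after its values were seen. Chance is therefore not excluded for Acot4, and it fell short of the threshold with the block and the GC slope together. Acot4 overlaps an antisense gene, and among its paralogs Acot2 differed by 0.65 (adjusted p = 0.168; 0.049 with the GC slope as a covariate) and Acot6 by -0.09 (0.827). As groups, early receptor-induced genes (median 0.44, camera adjusted p = 0.0493), mitochondrially encoded genes (-0.49, 0.00262) and cytosolic ribosomal proteins (0.65, 0.0493) also differed, and 46 of 100 splits gave as many lists, with up to 12, so chance cannot be excluded for the 3 lists. These lists lost the call with an estimated correlation (adjusted p = 0.893). The early genes turned, with the GC slope as a covariate, to -0.13 (0.00917) and the mitochondrially encoded genes to 0.11 (0.00521), and the ribosomal proteins lay at -0.00111 (0.803).

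Libraries of the same group deviated from each other along a shared axis, which held 62.2% of the residual variance. The loading of genes on this axis correlated across genes with transcript GC content (r = 0.767) and less with length (r = -0.232), which is consistent with a GC-dependent step of library preparation or amplification. Runs of library numbers as its whole cause would leave almost none of its sum of squares within runs. The share within runs was 60.5% ± 20.4, which argues against runs as the whole cause. Whether they are part of it stays open. No biological explanation was tested, as the design names none within a group.

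With the block for runs of library numbers, 887 genes passed between genotypes in unstimulated culture, where 0 passed without it. The GC trend is a candidate explanation, as 0 of the 887 stayed past the threshold with the block and the GC slope together, the median size of their difference being 0.681 before and 0.202 after, with a median SE of 0.176 and 0.119. The calls ended because the differences shrank more than their errors. After removal of the GC trend from each library 45.2% of the median size was left (0.308), 360 genes passed and 245 of them were among the 887. A genotype effect apart from the GC trend therefore stays open and cannot be told apart from it, since the GC slope separated the genotypes fully in this condition.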

How the results depend on the processing

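The alternatives with a GC correction and those without the pair of libraries farthest in GC slope were tests chosen only after the result was seen, and the others were planned. The 2 planned count tools were not run. The cause was not tested for any change given here, except that a higher minimum left out Sall1 and Acot4. Zfp488 was still tested with that minimum and no longer passed on average. A fit of only the groups compared used fewer libraries and took the spread from those groups alone. The SD of the GC slope was 0.245 in the fresh cKO libraries. It was 0.060 in cKO and 0.088 in control libraries after unstimulated culture. The differences between the unstimulated groups are the same in a fit of only these groups and without the pair farthest in GC slope. Their counts could thus move only through the estimated errors, the moderation and the genes tested. Which of these moved the counts, and whether the spread in GC slope was behind it, was not tested. Of 4699 alternative results for 226 pairs of a named gene and a comparison, 4257 kept their direction and side of the threshold, 256 kept the direction without passing any longer, 162 kept it and passed newly, and 24 reversed. Depth is unknown, so the counting error of low genes such as Creld1, Acot4 and Sall1 could not be given. The largest shift of a library by the TMM-type scaling was 0.0639.

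Filters and scaling moved counts of genes between genotypes and with stimulation. Between genotypes in fresh cells the count was 0 with a minimum of 50, and 0 when only the groups compared were fitted, where 1 was found as planned. In unstimulated culture it was 2 with a pseudocount of 5, 2 with a pseudocount of 0.5, 5 without a filter, 2 with TMM-type scaling, 1 after quantile normalization and 2 without the trend, against 0. For the mean genotype effect it was 1 without a filter, 0 with a minimum of 50, and 1 with TMM-type scaling or quantile normalization, against 2. Quantile normalization gave 60 stimulation genes in control cells against 38, and the interaction with stimulation had 3 genes without a filter and 0 with a minimum of 50, against 1. A fit of only the groups compared gave 3737 genes between genotypes in unstimulated culture (1262 higher, 2475 lower), 7 and 2349 for stimulation in control and cKO cells, 2373 for its interaction and 811 for culture in cKO cells.

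Library weights from limma stopped before convergence, with weights from 0.0122 to 14.2, and their counts are given with that limit. They were 7292 between genotypes in unstimulated and 2344 in stimulated culture, 3569 for the mean genotype effect, 6301 and 6169 for stimulation in control and cKO cells, 7103 for its interaction and 6444 for culture in control cells.

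The GC slope as a covariate gave 9 genes for the mean genotype effect, 321 and 72 for stimulation in control and cKO cells and 4940 for culture in cKO cells. GC-corrected values gave 1 gene between genotypes in unstimulated culture and 6 on average, 131 and 183 for stimulation and 3776 for culture in cKO cells, and the correlation of stimulation effects across genes was -0.0740. All 38 stimulation genes of control cells and 30 of the 31 of cKO cells were among those called with the covariate. The pair of libraries farthest in GC slope are Creld1 cKO fresh replicates 2 and 3, so 1 library is left in that group and is assumed to vary like the other groups. Without them the counts were 2782 between genotypes in unstimulated culture, 1 on average, 98 and 139 for stimulation and 1384 for its interaction. Creld1 in stimulated culture was -0.52 with the covariate and -0.53 with GC-corrected values, both past the threshold over the 3 conditions.

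Runs of library numbers were not taken to pair the libraries, as 25 of the 45 pairs from the same run correlated over 0.1 (range -0.683 to 0.689), and no label ties a run to a batch. Of 18 libraries 10 correlated best with one of their own run, against a mean of 5.95 in 10000 shuffles of the runs within groups, of which 7.09% gave as many, so chance is not excluded. The block for these runs gave 887 genes between genotypes in unstimulated culture (161 higher, 726 lower), 7 on average and 153 for stimulation in cKO cells, and changed no other count by over 1.5 times. The block with the GC slope gave 11 genes on average, 240 and 139 for stimulation in control and cKO cells, 0 for its interaction, 5009 for culture in cKO cells and 1 for the culture interaction. With it Creld1 was -0.45 in unstimulated culture, short of the threshold over the 3 conditions, and -0.54 in stimulated culture, past it.

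Counts of lists were mostly lost with an estimated correlation, which left 0 between genotypes in fresh, unstimulated and stimulated cells and on average, 0 for stimulation in control cells, 0 for its interaction and 3 for culture in control cells, against 5, 2, 2, 5, 11, 3 and 9. The self-contained test fry left 0 for these genotype effects and the interaction and 2 for stimulation. In fresh cells 8 lists were called after quantile normalization and 1 without the pair farthest in GC slope, where 1 cKO library stood against 3 controls. In unstimulated culture 4 were called without a filter, and 1 with quantile normalization, library weights or GC-corrected values. In stimulated culture 1 was called with quantile normalization or library weights. On average 3 were called with a minimum of 50 and 1 with GC-corrected values. For the interaction 1 was called with a pseudocount of 5, a minimum of 50, library weights, GC-corrected values or ranks.

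Leaving out each library in turn gave 1 to 1193 genes between genotypes in fresh cells (highest without Creld1 cKO fresh replicate 3), 0 to 1 in unstimulated and 0 in stimulated culture, and 1 to 1613 on average (highest without the same library). It gave 4 to 78 for stimulation in control and 11 to 34 in cKO cells, 1 for its interaction, 2103 to 2675 and 1736 to 3322 for culture, and 0 for its interaction. Lists ranged from 1 to 6, 1 to 2 and 0 to 8 between genotypes, 1 to 6 on average, 7 to 12 for stimulation, 1 to 3 for its interaction and 8 to 9 for culture. Creld1 ranged from -0.64 to -0.29 in fresh cells, -1.15 to -0.81 in unstimulated and -0.53 to -0.18 in stimulated culture. Correlations of genotype effects ranged from 0.05 to 0.81, -0.56 to 0.03 and -0.75 to -0.14, and that of stimulation effects from -0.60 to -0.14. A library left out leaves groups of 2 whose spread is shared with the other groups.

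The genes that reversed had not passed in these comparisons. With the GC slope as a covariate, and with the block added to it, mt-Nd5 between genotypes in unstimulated culture was -0.12 and -0.14 against 0.38, and for the interaction with stimulation Ier2 was -0.13 and -0.033 against 1.29, mt-Nd4l 0.043 and 0.073 against -0.60, Acot6 0.39 and 0.51 against -0.09 and Creld1 -0.037 and -0.090 against 0.64 (-0.12 with GC-corrected values). The stimulation effect on Creld1 in cKO cells was -0.055 with the covariate, -0.11 with GC-corrected values and -0.087 with block and GC slope, against 0.35. In control cells it was 0.00550 with GC-corrected values and 0.00298 with block and GC slope, against -0.29. The culture effect on Creld1 in cKO cells was 0.16 with library weights, and -0.27 to 0.086 with each library left out. The culture interaction of Oas2 was -0.043 without the pair farthest in GC slope, and -0.029 to 0.11 with each library left out. With each left out, Zfp488 in fresh cells ranged from -0.00323 to 0.25 and the interaction of Acot6 from -0.19 to 9.4e-04.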

Other observations

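The tests of the isolation-response genes and of the genes raised by stimulation were chosen only after the result was seen, as was the list of isolation-response genes itself. The splits and the test of the chromosome neighbours of Creld1 were planned. The test of the neighbours of Sall1 was written before its result was seen, but for a gene chosen after its values were seen.

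Genes of survival, division and lineage went both ways after unstimulated culture, the examples being chosen after their values were seen. In control and cKO cells the survival gene Bcl2 (-0.88 and -0.98), the apoptotic regulator gene Pmaip1 (-0.85 and -0.85) and the replication clamp gene Pcna (-0.86 and -0.99) fell, while the initiator caspase gene Casp9 rose by 0.74 and 0.77 and the cell cycle inhibitor gene Cdkn1a by 1.00 and 0.97 (limma, n = 3 libraries per group). Of the T helper lineage genes, the nuclear receptor gene Rora rose by 0.52 and 0.77 and the repressor gene Prdm1 by 0.55 and 0.68, whereas Stat3 (-0.51 and -0.52) and Runx1 (-0.58 and -0.49) fell. The interferon gamma receptor genes went apart, Ifngr1 rising by 0.91 and 0.88 and Ifngr2 falling (-0.58 and -0.31). All of these passed the test in both genotypes.

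Early response genes such as Fos, Jun and Dusp1 were lower after culture than in freshly isolated cells. A candidate explanation is a response to isolation and sorting in the fresh cells, and of 38 genes written down for such a response 35 were tested and 24 were not raised by stimulation, of which 4 are also early receptor-induced and 6 also heat shock genes. As the list was written after these falls were seen, it is no independent support and the explanation stays open, although of the 24 genes 79.2% were lower in control and 91.7% in cKO cells (medians -0.83 and -1.01), with 16 and 19 called lower and 1 and 0 called higher. T cell receptor signalling in the fresh cells cannot be told apart either, as the 12 genes raised by stimulation in both genotypes had median changes of -0.24 ± 0.21 and -0.31 ± 0.19 (SE) that decide nothing, since the unstimulated libraries used to select them also pull these medians below 0, and the 30 and 34 genes selected in the other genotype, which shares no library, had -0.14 ± 0.17 in control and -0.094 ± 0.082 in cKO cells and went both ways (11 and 8 called lower, 2 and 5 higher). The GC trend as the whole cause is argued against, as the median over all 35 tested genes of the list was -0.827 and -1.04 before and -0.902 and -1.01 after its removal, at least 97.2% being left, and other effects of culture on these transcripts, such as loss of signals present in the animal, were not tested.

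The higher Sall1 level was not shared by its surroundings, as the 8 other tested genes within 2 Mb had a median genotype difference of 0.0274 ± 0.0365. The 48 tested genes within 5 Mb of Creld1 lay at percentile 26.6 of 9821 windows of as many genes in the size of their genotype difference. Of these genes 1 had an unadjusted p under 0.05 by limma and 0 passed the threshold. A wide change of the window was thus not seen. DNA of another strain around the targeted allele is not excluded, as a median can miss changes of a few genes. Were the control mice to carry the same allele, both genotypes would share this DNA and no difference could show.

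Regrouping the libraries gave these results. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Between genotypes, the real split gave 1 gene in fresh cells, 2 of 10 splits gave as many and the highest other gave 5424, and the counts of lists were 5 real and 6 highest other, with 5 of 10 splits as large. In unstimulated culture the real and highest other counts were 0 and 0 genes (10 of 10) and 2 and 4 lists (4 of 10), and in stimulated culture 0 and 0 genes (10 of 10) and 2 and 10 lists (8 of 10). Stimulation gave 38 genes in control and 31 in cKO cells and culture 3151 and 2408, each in 1 of 10 splits, with 0 in the highest other split, while 11 stimulation lists stood against 13 and 9 culture lists against 13 (3 of 10 for both). For the mean genotype effect 3 of 100 splits gave as many as 2 genes, a share under 0.05. The highest other split gave 3686 genes, so this count does not exclude chance for Sall1 or Zfp488. As many as 5 lists were given by 26 of 100 splits, with up to 10. For the culture interaction all 100 splits gave at least the 0 genes observed, with up to 6693.

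The split with 5424 genes points to a structure of the fresh libraries that follows the GC slope. It set control replicate 1 and Creld1 cKO replicates 1 and 2, with slopes of -0.161, -0.193 and -0.312, against control replicates 2 and 3 and Creld1 cKO replicate 3, with 0.0827, 0.0638 and 0.159. The splits with 3686 and 6693 genes divided the fresh libraries in the same way.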
